A study of Homo sapiens with 10 samples.

How the data were processed

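RNA from 10 samples of a human embryonic stem cell line was measured on Illumina expression beadchips, 1 array per sample. The line carries an enhanced GFP reporter in one NKX2-5 allele and a MYC gene under a Tet-ON promoter, which is switched on by a tetracycline such as doxycycline. Per the labels' protocols, cells were grown as embryoid bodies for 6 days, dissociated, kept for 6 more days in an expansion culture and then sorted on the reporter and on the surface protein podoplanin (PDPN). Total RNA was amplified and labelled with biotin. Each of the 5 sorted populations had 2 biological replicates. The labels do not say whether a replicate number marks a shared culture or day, so the numbers were not used to pair samples in the main analysis. A culture shared by some of the populations was thus not modelled.

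The values analysed are the authors' processed values, as deposited, on a log scale taken here as log2. The labels and the file headers used here give neither the base nor the background treatment nor the between-array normalization. A base of 10 would give the widest probe a range of 6.64 decades over the 10 arrays and was set aside. A natural log could not be excluded, and under it every difference would stand for a larger fold. The authors' values were centred: after the repair described next, the median over the 10 arrays was 0 for all 47323 probes within 1e-05. Levels of different genes can therefore not be compared, no filter on dim probes was possible, and a probe near 0 on every array can be unexpressed or evenly expressed. The medians of the arrays over all probes lay between -0.04 and 0.04. No background level is known, so the number of arrays sets the precision.

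Part of the deposited log2 values had lost their decimal point. In 1180 cells the point after the first digit was missing, in 7203 cells a value in exponent notation had been rewritten without its exponent, and 6 further cells had a short form of the same damage. These 8389 of 473230 cells (1.77%) were restored from the number of digits alone. The result was checked in 4 ways: by the probe medians, by an unbroken density at the affected sizes (274 cells from 0.9 up to 1 and 227 from 1 up to 1.1), by the correlation of replicates over probes with a lost point (Pearson's r across probes of 0.90 to 0.99 in the 5 populations), and on simulated values, of which 99.98% of 99616 came back. The probe medians are no check of the 6 short forms. The simulated values were damaged in the assumed way, so they test the repair and not that assumption. A second table of unnormalized signals and detection p-values was not used here. Its 22 columns of per-sample values, 11 of them signals, carry running numbers that match no sample label.

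Probe names came from the platform annotation table supplied with the values. Of the probes, 30113 had 1 gene symbol, 8 had several and 17202 had none. The symbols were compared with a current RefSeq table through the gene identifiers, which were found for 30074 probes. The 20046 named genes were tested with 1 probe each. For the 6691 genes with more than 1 probe, the probe with the largest variance over all 10 arrays was taken, without use of the population labels. This variance includes differences between populations, so the rule favours the probe that differs most. The adjustment of p-values over genes does not allow for this choice.

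The plan fixed before the data were examined was to normalize the unnormalized signals, to filter on detection and to keep the brightest probe of each gene. The values at hand did not allow this. The authors' values, which the plan held as an alternative, became the main data, the detection filter was dropped and the probe rule was changed as given above. The tests stayed as planned. A linear model with a mean per population was fitted to all 10 arrays with limma 3.58.1 (lmFit and eBayes with default settings) in R 4.3.3. All populations share the estimate of spread, with 5 residual and 9.28 prior degrees of freedom. The comparisons were Pop 2 minus Pop 3, Pop 6 minus Pop 7, the difference between these differences (interaction), the mean of Pops 6 and 7 minus the mean of Pops 2 and 3, Pop 1 minus Pop 2, and an F test of any difference among the 5 populations. P-values were two-sided and adjusted by the Benjamini-Hochberg method over 20046 genes, with a threshold of 0.05. Values after ± are standard errors of the model for differences and SDs for population values.

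Gene lists were fixed before the data were examined: 31 lists of heart and other cell lineages, signalling targets, growth and metabolism, stress and housekeeping genes, with 495 entries, of which 458 were measured under the same symbol and the others were not analysed here. Each list was tested with limma's camera at a preset correlation of 0.01, adjusted over the 31 lists within a comparison, and again with an estimated correlation and with fry. The genes named are NKX2-5, PDPN and MYC in every comparison, the 8 largest and 8 smallest differences past the threshold whose replicates do not overlap between the compared populations (6 and 6 for the interaction), and up to 4 members past the threshold, or 2 below it, of each list described. Names that are only a locus or clone identifier were left out. Members whose call was lost in many alternatives were not always named, and genes named outside the rule are marked as such.

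The fit was tested on simulated data in which 50 genes of each size changed on the spread of the real arrays. In the simulation of Pop 2 minus Pop 3 over 20046 genes, 70.0% of changes of 0.5 and 96.0% of changes of 1 were called. For the interaction 26.0% and 84.0% were called. Many genes changed together in each simulation, and the spread of a gene was shared by all populations. On the real arrays the smallest difference called in Pop 2 minus Pop 3 was 0.71. The simulated shares thus do not carry over to a comparison with few changed genes. Alternatives were every probe tested by itself, the mean of a gene's probes, array quality weights, only the populations of a comparison, the replicate number as a block, a minimum difference of 1, other pairs of populations, other list tests, and each array left out in turn. Chosen after seeing the data were array medians set to 0, quantile normalization of the centred values, robust variances, and the more variable genes alone. Scripts used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib for the plots.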

Results

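Expression was profiled in 5 populations sorted from expansion cultures of NKX2-5eGFP/w Tet-ON MYC human embryonic stem cells, a line whose green fluorescence reports NKX2-5, a transcription factor of early heart cells. Each population had 2 biological replicates and 1 array per replicate. Pop 1 was NKX2-5-negative with high PDPN, Pop 2 was NKX2-5-negative and PDPN-positive, Pop 3 was negative for both, Pop 6 was positive for both, and Pop 7 was NKX2-5-positive and PDPN-negative. The cultures differed too, in what was added to a base that the labels call DSIS. Pop 1 received DMH1, an inhibitor of BMP type I receptors, with SU5402, an inhibitor of FGF receptors. Pops 2 and 3 received BMP4 with SU5402, and Pops 6 and 7 received BMP4 with bFGF. Only the comparisons of Pop 2 with Pop 3 and of Pop 6 with Pop 7 were thus made within the same supplements. All values are the authors' centred log values, taken as log2, so that 0 is a gene's median over the 10 arrays and not an absence of expression.

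The sort markers were measured first, as a check of the labels. NKX2-5 (probe ILMN_1800058) read 1.46 ± 0.13 in Pop 6 and 1.26 ± 0.15 in Pop 7 (SD, n = 2), against -0.03 ± 0.03 in Pop 1, -0.04 ± 0.06 in Pop 2 and -0.08 ± 0.07 in Pop 3. PDPN (probe ILMN_1670490) read 1.20 ± 0.25 in Pop 1, 0.26 ± 0.02 in Pop 2 and -0.87 ± 0.04 in Pop 3, and 0.00 ± 0.17 in Pop 6 against -1.01 ± 0.11 in Pop 7. Both genes thus followed the gates on every array. MYC (probe ILMN_1680618), which cannot be assigned to the transgene or the endogenous gene here, read 0.40 ± 0.11 in Pop 1, -0.44 ± 0.38 in Pop 2, -0.49 ± 0.38 in Pop 3, 0.01 ± 0.07 in Pop 6 and 0.12 ± 0.10 in Pop 7. In Pops 2 and 3 the first replicates read -0.71 and -0.75, against -0.17 and -0.22 in the second replicates. HSPA1A, named here after its values were seen, read -1.07 and -1.08 against -0.14 and 0.03 on the same arrays. Over genes, the replicate deviations of Pops 2 and 3 correlated at r = 0.15, below the r = 0.26 of Pops 1 and 2. Whether Pops 2 and 3 shared cultures can therefore not be decided from these values.

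**Figure D1:**
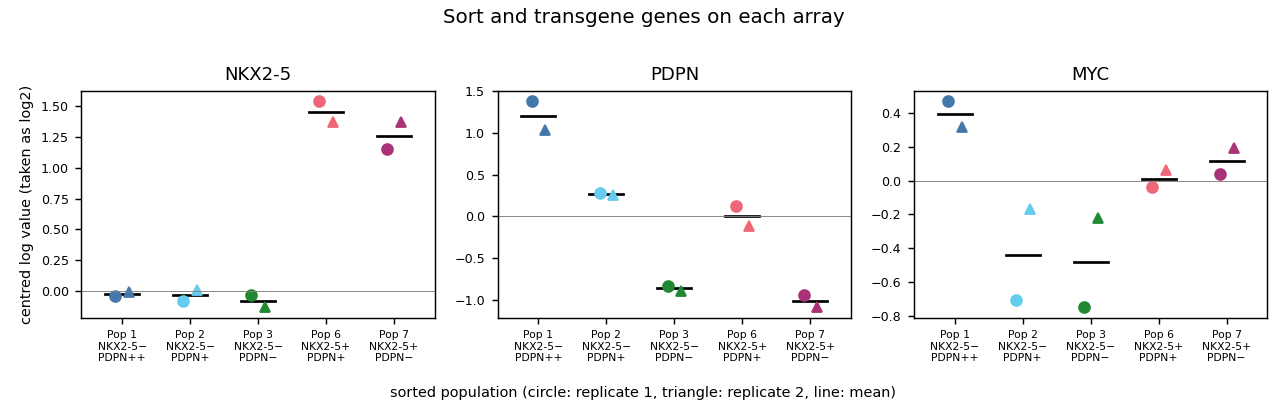
Centred log value (taken as log2, y axis) of NKX2-5, PDPN and MYC on each array of the 5 sorted populations (x axis), with circles for replicate 1, triangles for replicate 2 and a line at the mean. NKX2-5 lies at 1.15 or above in Pops 6 and 7 and near 0 elsewhere, and PDPN is highest in Pop 1 and lowest in Pops 3 and 7.

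Across all 5 populations 3203 of 20046 genes differed (limma F test, adjusted p under 0.05), 574 of them with a range of at least 1 between population means. Among these 3203 genes, the highest mean lay in Pop 1 for 951, in Pop 7 for 943, in Pop 2 for 494, in Pop 3 for 420 and in Pop 6 for 395. Pop 1 also held the lowest mean most often, for 1047 genes. Replicates correlated across genes at 0.81 in Pop 1, 0.80 in Pop 7, 0.77 in Pop 6, 0.48 in Pop 3 and 0.33 in Pop 2. The SD of the replicate difference over genes was 0.19 in Pop 2, 0.16 in Pop 3 and 0.13, 0.13 and 0.12 in Pops 1, 6 and 7. An 18S ribosomal RNA probe, RNA18SN5, named here after its values were seen, read 2.46 in Pop 1 replicate 2 and 1.62 in Pop 2 replicate 2, against 0.04 and -0.77 in their other replicates.

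Few genes passed the threshold between NKX2-5-negative cells with and without PDPN. By limma, 487 of 20046 genes had an unadjusted p under 0.05, a smaller share than chance alone gives on average. The model may thus overstate the error of this comparison, and a fit pairing the arrays of Pops 2 and 3 alone was not run. Few calls therefore do not show that the 2 populations are alike. Besides PDPN itself, which was higher in Pop 2 by 1.13 ± 0.11 (adjusted p = 8e-04), 3 genes passed the threshold, all lower in Pop 2. These were LUM (-1.11 ± 0.10, adjusted p = 0.00037) and DCN (-0.81 ± 0.09, adjusted p = 0.0013), which encode the small proteoglycans lumican and decorin of connective tissue matrix, and NLRP7 (-0.71 ± 0.09, adjusted p = 0.0056). LUM was far above the other populations in both, at 2.10 ± 0.18 in Pop 2 and 3.22 ± 0.07 in Pop 3. NKX2-5 (0.05 ± 0.10) and MYC (0.05 ± 0.17) did not differ (adjusted p = 1 each).

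Of the 20 measured members of the mesenchyme and matrix list, LUM and DCN fell and 18 did not pass, and 3 passed when adjusted over the list alone. Camera placed this list lower (adjusted p = 0.038), the 20 mitotic genes higher (adjusted p = 0.038) and the 10 housekeeping genes lower (adjusted p = 0.038), and no call held with an estimated correlation (adjusted p = 0.95 each). The mesenchyme call was also lost without Pop 2 replicate 2 or Pop 3 replicate 1 (adjusted p = 0.89 and 0.094), the mitotic call without Pop 2 replicate 1 or either Pop 3 array (adjusted p of 0.072 to 0.99), and the housekeeping call without Pop 3 replicate 1 or either Pop 2 array (adjusted p of 0.053 to 0.36). No mitotic or housekeeping gene passed by itself. TTK, a mitotic kinase, differed by 0.33 ± 0.12 and TOP2A, a topoisomerase of dividing cells, by 0.26 ± 0.08, while B2M differed by -0.22 ± 0.11 and RPL13A by -0.15 ± 0.11. The 4 calls in this comparison became 51 without Pop 2 replicate 2, of which 90.2% were higher in Pop 2. All 4 genes had other probes, and none of these was called. With the mean of a gene's probes 1 gene passed, LUM was the only call left, and PDPN, DCN and NLRP7 were lost. With Pops 2 and 3 fitted alone 2 genes passed, and DCN (adjusted p = 0.12) and NLRP7 (adjusted p = 0.26) were lost. The call of NLRP7 was also lost without Pop 2 replicate 1 (adjusted p = 0.067) and without Pop 3 replicate 1 (adjusted p = 0.11).

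Among NKX2-5-positive cells, 11 of 23 measured genes of the cardiac contractile apparatus were higher in Pop 6 than in Pop 7, by 0.44 to 2.53. MYH6, the alpha myosin heavy chain, was higher by 2.53 ± 0.16 (adjusted p = 6.3e-07), a 5.78-fold difference on a log2 scale. After quantile normalization of the centred values it was higher by 1.46 (adjusted p = 0.0045). MYH6 was the highest value on both Pop 6 arrays (5.13 and 5.16), and the highest values of the other arrays were 2.31 to 3.74. Quantile normalization replaces the highest value of each array by their mean, so the smaller MYH6 difference follows from its rank. The myosin light chain genes MYL3 (2.29 ± 0.09, adjusted p = 5.1e-09) and MYL7 (2.12 ± 0.10, adjusted p = 1.2e-08) and the M-band gene MYOM1 (1.79 ± 0.10, adjusted p = 9.4e-08) were higher as well. MYH6 read 5.15 ± 0.02 in Pop 6 and 2.62 ± 0.15 in Pop 7, whereas MYL3 read 0.10 ± 0.00 in Pop 7 and -0.14 ± 0.14 in Pop 2, and MYL7 read -1.68 ± 0.03 in Pop 7 and 0.09 ± 0.19 in Pop 2. In this list none fell and 12 did not pass, 15 passed when adjusted over the list alone, and the median difference was 0.37. The list was higher by camera (adjusted p = 5.1e-46), with an estimated correlation (adjusted p = 0.00065) and by fry (adjusted p = 1e-05).

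The other large differences toward Pop 6 were ACTA2, the smooth muscle actin that early cardiomyocytes also express (2.18 ± 0.12), CSHL1 (2.01 ± 0.08), the troponin gene TNNC1 (1.74 ± 0.11) and CKM, the muscle creatine kinase (1.47 ± 0.08). CSHL1 belongs to the growth hormone cluster, whose members are near-identical, and its 2 other probes were not called. SMYD1, a histone methyltransferase of striated muscle, was higher by 0.72 ± 0.08, the phospholamban gene PLN by 0.76 ± 0.10 and IRX3 by 0.76 ± 0.09. Camera also called the smooth muscle (2 of 12 rose), ventricular (1 of 10 rose), excitation and calcium handling (1 of 19 rose) and core transcription factor lists (1 of 14 rose), at adjusted p = 1.3e-07, 7e-06, 0.0031 and 0.02. The second smooth muscle gene was TPM2 (0.41 ± 0.08, adjusted p = 0.037), which passed in 10 of the 20 settings run. It was lost without any single array of Pop 1, Pop 6 or Pop 7 (adjusted p of 0.076 to 0.53) and with the mean of its probes (0.06, adjusted p = 1), and 1 of 12 passed without any single array of Pops 6 and 7. With an estimated correlation these calls were lost, at adjusted p = 0.051, 0.051, 0.084 and 0.16, and the transcription factor call was also lost without Pop 6 replicate 1 (adjusted p = 0.14) and without Pop 7 replicate 1 (adjusted p = 0.05). The posterior heart field and atrial list was higher as well (2 of 13 rose, camera adjusted p = 7.6e-05, and adjusted p = 0.051 with an estimated correlation). The 2 were MYH6 and MYL7, which are also in the sarcomere list, and the median of the atrial list was 0.04. With no gene past the threshold, camera placed p53 targets higher (adjusted p = 0.026) and MYC targets in ribosome biogenesis (adjusted p = 0.01), dissociation and heat shock genes (adjusted p = 0.025) and FGF and ERK targets (adjusted p = 0.029) lower in Pop 6. None of these 4 calls held with an estimated correlation (adjusted p = 0.43, 0.35, 0.17 and 0.17). NKX2-5 differed by 0.20 ± 0.10 (adjusted p = 0.83) and MYC by -0.11 ± 0.17 (adjusted p = 1), while PDPN was higher by 1.01 ± 0.11 (adjusted p = 0.00026).

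The largest differences toward Pop 7 included several genes of extracellular matrix. ANXA1 (annexin A1) differed by -1.07 ± 0.11, the collagen genes COL3A1 and COL5A2 by -1.04 ± 0.15 and -1.0 ± 0.10, HAPLN1, a link protein of hyaluronan matrix, by -1.02 ± 0.10, and the forkhead gene FOXD1 by -0.97 ± 0.08. ARHGDIB (-0.97 ± 0.09), MARCKS (-0.95 ± 0.09) and PRPH, the neuronal filament peripherin (-0.94 ± 0.12), completed the set. In the mesenchyme and matrix list 3 of 20 genes fell, the third being TGFBI (-0.72 ± 0.09), 2 to 5 passed when an array was left out, and 8 passed when adjusted over the list alone. The list was lower by camera (adjusted p = 2.1e-05) but not with an estimated correlation (adjusted p = 0.2). Of markers of other lineages, SOX18 (endothelial, -0.67 ± 0.08) was lower in Pop 6, as the single change among 19 endothelial genes (camera adjusted p = 0.25), and so was TUBB3 (neural, -0.46 ± 0.08, named outside the rule), as the single change among 13 neural genes (camera adjusted p = 0.97), a call lost without any single array of Pops 6 and 7. EPCAM (epithelial, 0.81 ± 0.12) was higher, as the single change among 12 endoderm and epithelial genes, a list called by camera (adjusted p = 0.029) and not with an estimated correlation (adjusted p = 0.35), nor without Pop 6 replicate 2 (adjusted p = 0.27) or Pop 7 replicate 1 (adjusted p = 0.16) or with the mean of a gene's probes (adjusted p = 0.12).

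In all, 101 genes passed between Pops 6 and 7, 60 higher and 41 lower in Pop 6, and 23 differed by at least 1. The count was 53 without Pop 7 replicate 2, 58 without Pop 6 replicate 1 and 61 without Pop 7 replicate 1, and rose to 203 when the 2 populations were fitted alone and to 181 with array weights. The call of COL3A1 was lost without each of those 3 arrays (adjusted p = 0.066, 0.057 and 0.052), as was that of EPCAM (adjusted p = 0.056, 0.075 and 0.062), and the call of PLN without Pop 7 replicate 2 (adjusted p = 0.053).

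**Figure D2:**
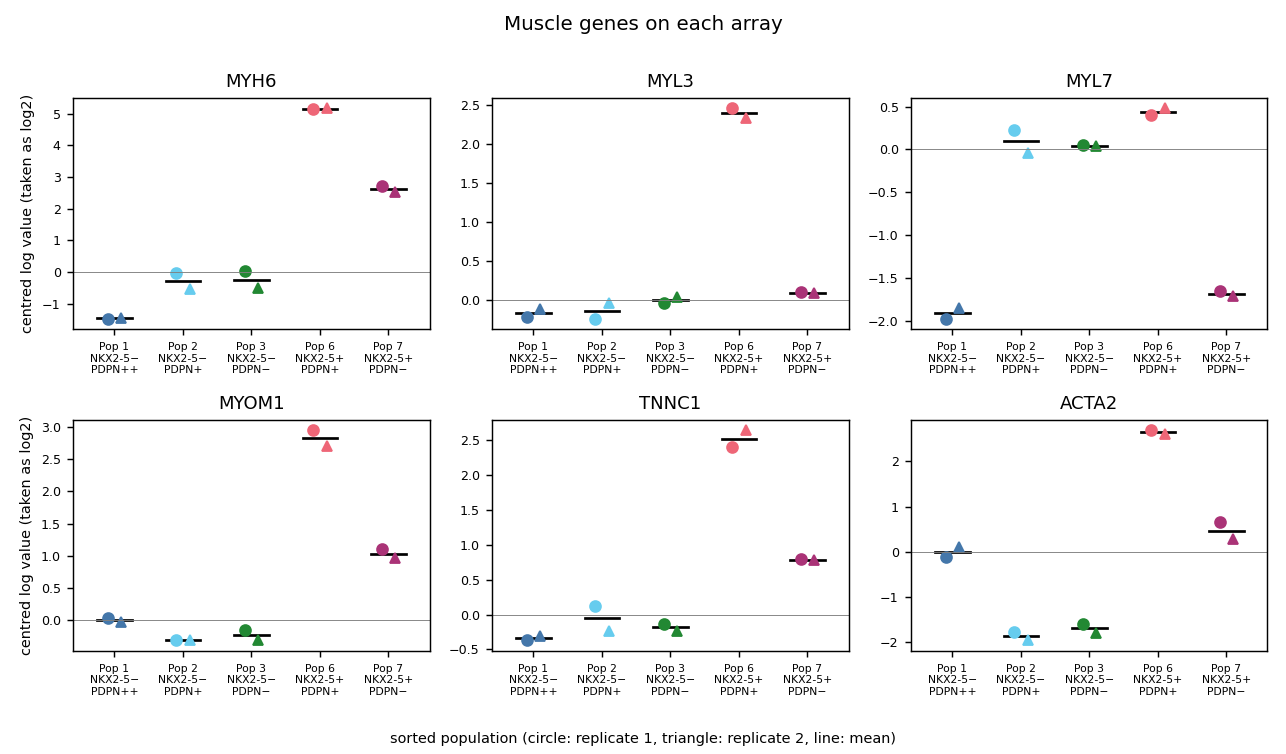
Centred log value (taken as log2, y axis, a scale per panel) of 6 muscle genes on each array of the 5 sorted populations (x axis), with circles for replicate 1, triangles for replicate 2 and a line at the mean. In every panel both Pop 6 arrays lie above both Pop 7 arrays, by 2.53 for MYH6 and 2.29 for MYL3 between the means.

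Whether the PDPN contrast depends on the NKX2-5 reporter was tested as an interaction, which also spans the change of supplement from SU5402 to bFGF. Muscle genes gave the largest interactions. The Pop 6 to Pop 7 difference exceeded the Pop 2 to Pop 3 difference by 2.58 ± 0.23 for MYH6 (adjusted p = 5.2e-05), 2.43 ± 0.13 for MYL3 (adjusted p = 2.8e-07), 2.36 ± 0.17 for ACTA2 (adjusted p = 5.1e-06), 2.08 ± 0.14 for MYL7 (adjusted p = 1.9e-06) and 1.88 ± 0.14 for MYOM1 (adjusted p = 5.1e-06). CSHL1 gave 2.01 ± 0.12. The Pop 2 to Pop 3 differences of these genes lay between -0.18 and 0.05, so their interactions are close to the Pop 6 to Pop 7 differences. Whether the genes are expressed in Pops 2 and 3 is not known here, and an unexpressed gene could show no difference there. Of 23 sarcomere genes 7 passed, all positive, and 14 did when adjusted over the list alone (camera adjusted p = 3.1e-38, and adjusted p = 0.001 with an estimated correlation). In the smooth muscle list ACTA2 passed and 11 genes did not (camera adjusted p = 6.2e-05, and adjusted p = 0.12 with an estimated correlation).

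Matrix genes split in this test. LUM (1.39 ± 0.14) and DCN (0.82 ± 0.12) were positive, since both were lower in Pop 2 than in Pop 3 and near 0 in Pops 6 and 7, whereas COL3A1 (-1.23 ± 0.21) and COL5A2 (-1.04 ± 0.14) were negative, as was TGFBI. With 2 positive and 3 negative calls among 20, the list was not called (camera adjusted p = 0.18), except without Pop 2 replicate 2 (adjusted p = 0.0067). When an array was left out 1 to 7 of the 20 passed, the lowest count being without Pop 7 replicate 2. Negative interactions outside that list included MARCKS (-1.02 ± 0.13), HAPLN1 (-0.98 ± 0.14), FOXD1 (-0.97 ± 0.12) and CCND2, cyclin D2 (-0.91 ± 0.12). For the sort genes the interaction was 0.15 ± 0.13 for NKX2-5, -0.12 ± 0.16 for PDPN and -0.16 ± 0.24 for MYC (adjusted p = 1 each). In all 46 genes passed, 33 positive (71.7%). The count became 186 without Pop 2 replicate 2, with 22.0% positive, and 30, 24, 25 and 18 without Pop 3 replicate 1, Pop 6 replicate 1, Pop 7 replicate 1 and Pop 7 replicate 2. After quantile normalization of the centred values it was 26 (84.6% positive). MYH6 (1.48, adjusted p = 0.091), MARCKS (-0.89, adjusted p = 0.16), CCND2 (-0.70, adjusted p = 0.092) and COL3A1 (-1.31, adjusted p = 0.091) were then no longer called. The smaller MYH6 value follows from its rank on the Pop 6 arrays, as given above. COL3A1 passed in 8 of the 20 settings run. It was also lost without either array of Pop 6 or Pop 7, either array of Pop 1 or Pop 3 replicate 1 (adjusted p of 0.19 at most). With little change in the difference (-1.23 or -1.24) it was lost with only the populations of the comparison (adjusted p = 0.053), the mean of a gene's probes (adjusted p = 0.059), array medians set to 0 (adjusted p = 0.083) and robust variances (adjusted p = 0.13). DCN was lost without Pop 6 replicate 2 or either Pop 7 array (adjusted p of 0.078 at most) and with the mean of its probes (0.27, adjusted p = 0.72), and COL5A2 without Pop 7 replicate 2 (adjusted p = 0.06).

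Pops 6 and 7, sorted for the reporter and grown with bFGF, were then set against Pops 2 and 3, without the reporter and grown with SU5402. Reporter and supplement changed together, so a difference belongs to their combination. NKX2-5 was higher by 1.42 ± 0.07 (adjusted p = 6.8e-10). Targets of FGF and ERK signalling were higher: 12 of 18 rose, none fell, and 13 passed when adjusted over the list alone. They included the cyclin gene CCND1 (1.94 ± 0.07, adjusted p = 3.8e-11), the feedback inhibitor genes SPRY2 (1.26 ± 0.08) and SPRY1 (1.22 ± 0.07), and DUSP6, a phosphatase gene acting on ERK (1.00 ± 0.07, adjusted p = 3.5e-08). The list was called by camera (adjusted p = 8.8e-14) and with an estimated correlation (adjusted p = 0.0091).

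Several heart muscle genes were higher as well. MYL7 read 0.44 in Pop 6 but -1.68 in Pop 7, against 0.09 in Pop 2 and 0.05 in Pop 3. MYH6 differed by 4.15 ± 0.12 (adjusted p = 2.2e-12), a 17.7-fold difference on a log2 scale, SMYD1 by 3.56 ± 0.06, ACTA2 by 3.33 ± 0.09, MYOM1 by 2.20 ± 0.07, the cardiac actin gene ACTC1 by 2.18 ± 0.13 and the atrial light chain gene MYL4 by 2.04 ± 0.07. Of 23 sarcomere genes 11 rose, 2 fell and 10 did not pass, and 15 passed when adjusted over the list alone (camera adjusted p = 5.9e-12, and adjusted p = 0.0091 with an estimated correlation). The sarcomere list differed between Pops 6 and 7, with means over the arrays of 1.07 and 1.08 in Pop 6, 0.30 and 0.30 in Pop 7, -0.05 and -0.07 in Pop 2 and -0.02 and -0.08 in Pop 3. Of 14 genes in the core cardiac transcription factor list 4 rose, namely NKX2-5, ISL1 (0.96 ± 0.06), MEF2C (0.73 ± 0.08) and the methyltransferase gene SMYD1, and 4 fell. The list had a median of -0.05 and a mean of 0.36 and was not called (camera adjusted p = 0.11).

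Outside the lists, the largest higher values were those of GBP2, an interferon-inducible GTPase (3.40 ± 0.06), GNG11 (2.98 ± 0.06), the tight junction gene CLDN11 (2.87 ± 0.09) and SNORD3A, the U3 small nucleolar RNA (2.65 ± 0.15). SNORD3A has near-identical copies elsewhere in the genome. COL1A2, a chain of type I collagen, was higher by 3.02 ± 0.08 while COL3A1 was lower (-1.39 ± 0.11), and LUM (-2.80 ± 0.07) and the PDGF receptor gene PDGFRA (-1.58 ± 0.07) were lower as well. In the mesenchyme and matrix list 5 of 20 rose, 9 fell and 14 passed when adjusted over the list alone (camera adjusted p = 0.018, and adjusted p = 0.47 with an estimated correlation). The other lowest values were those of MOXD1 (-3.03 ± 0.07), TMEM200A (-2.48 ± 0.06), the cartilage collagen gene COL2A1 (-2.41 ± 0.08), MFAP4 (-2.38 ± 0.06), SLITRK4 (-2.37 ± 0.08), HOXB5 (-2.37 ± 0.07) and CCND2 (-2.31 ± 0.06).

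Several further lists were called by camera and by fry, and each lost its camera call with an estimated correlation. NOTCH signalling genes were higher (6 of 12 rose, 1 fell, adjusted p = 1.8e-05, and adjusted p = 0.19 with an estimated correlation), with the effector genes HEY1 (1.63 ± 0.12), HEY2 (0.85 ± 0.06), HES4 (0.85 ± 0.07) and HEYL (0.72 ± 0.06). Hypoxia and glycolysis genes were higher (8 of 16 rose, 2 fell, adjusted p = 1.8e-05, and adjusted p = 0.35 with an estimated correlation), among them NDRG1 (1.09 ± 0.07) and the glucose transporter gene SLC2A3 (0.92 ± 0.06), but not the adrenomedullin gene ADM (-0.83 ± 0.10). Hedgehog targets were lower (5 of 9 fell, adjusted p = 6.1e-05, and adjusted p = 0.13 with an estimated correlation), CCND2 and the forkhead genes FOXF2 (-1.64 ± 0.06) and FOXF1 (-0.54 ± 0.06) among them. DNA replication genes were lower by smaller amounts (10 of 20 fell, adjusted p = 1e-04, and adjusted p = 0.47 with an estimated correlation), such as MCM3 (-0.48 ± 0.09) and MCM2 (-0.48 ± 0.08). Mitotic genes were lower too (10 of 20 fell, adjusted p = 5e-04, and adjusted p = 0.4 with an estimated correlation), such as TOP2A (-0.46 ± 0.06) and AURKB (-0.41 ± 0.07). In the retinoic acid and HOX list 4 of 14 fell (adjusted p = 0.041, and adjusted p = 0.35 with an estimated correlation), led by HOXB5 and HOXB2 (-0.63 ± 0.07). This list also lost its camera call without Pop 2 replicate 1 (adjusted p = 0.094), Pop 3 replicate 2 (adjusted p = 0.095), Pop 6 replicate 2 (adjusted p = 0.056) or Pop 7 replicate 1 (adjusted p = 0.076), with the replicate number as a block (adjusted p = 0.05, at the threshold) and with every probe tested by itself (adjusted p = 0.062). The mesenchyme list lost its call without Pop 2 replicate 1 (adjusted p = 0.054) and with the mean of a gene's probes (adjusted p = 0.064).

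Altogether 3107 genes passed, 1533 higher (49.3%) and 1574 lower, and 228 differed by at least 1. The median difference over all genes was -0.05. With array medians set to 0, 60.9% of the calls were higher, so the split between directions depends on the scaling. Pop 6 minus Pop 2 gave 1648 calls and Pop 7 minus Pop 3 gave 1897. MYC was higher by 0.52 ± 0.12 (adjusted p = 0.006), but not with the mean of its probes (0.24, adjusted p = 0.07). PDPN differed by -0.20 ± 0.08 (adjusted p = 0.11). It passed narrowly in 1 of the 20 settings run, with the replicate number as a block (adjusted p rounding to 0.05).

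**Figure D3:**
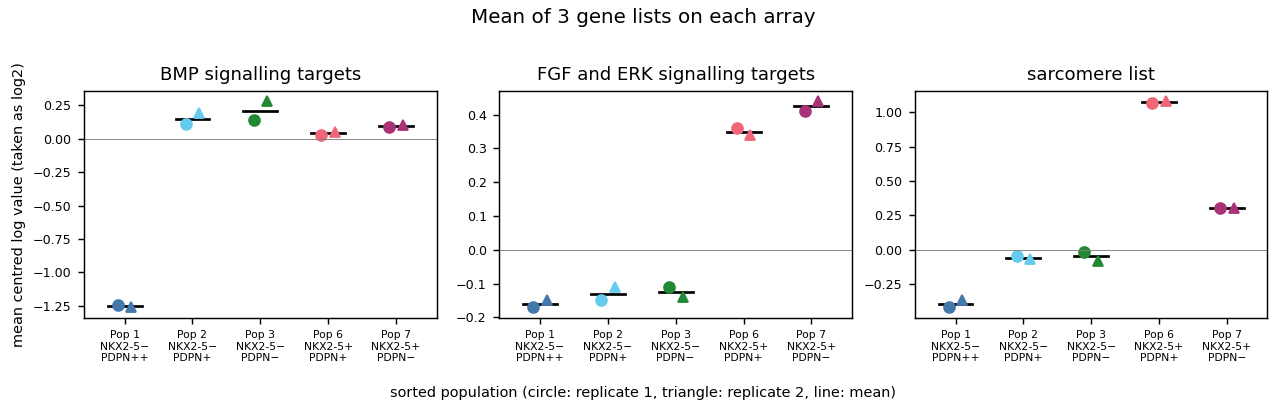
Mean centred log value (taken as log2, y axis, a scale per panel) of the measured genes of 3 lists on each array of the 5 sorted populations (x axis), with circles for replicate 1, triangles for replicate 2 and a line at the mean. BMP targets lie at -1.24 and -1.26 in Pop 1 and above 0 elsewhere, FGF and ERK targets lie above 0 in Pops 6 and 7 alone, and sarcomere genes are highest in Pop 6.

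Pop 1 and Pop 2 were both NKX2-5-negative and grown with SU5402, and differed in PDPN level and in DMH1 against BMP4. Targets of BMP signalling were far lower in Pop 1: 12 of 15 fell, 1 rose (BMPER, a secreted BMP-binding protein, named outside the rule), and 14 passed when adjusted over the list alone. TBX2, a T-box repressor gene, was lower (-4.14 ± 0.09, adjusted p = 4e-13), a 17.6-fold difference on a log2 scale. SMAD6, a feedback inhibitor of the pathway, differed by -3.43 ± 0.15 (adjusted p = 8e-10), ID2 by -2.88 ± 0.10 and ID1 by -2.31 ± 0.10 (adjusted p = 1.1e-09). The list was called by camera (adjusted p = 4.7e-23), with an estimated correlation (adjusted p = 0.03) and by fry (adjusted p = 3e-05). Of 18 FGF and ERK targets SPRY1 (0.81 ± 0.10) and PHLDA1 (0.59 ± 0.10) rose and CCND1 fell (-1.62 ± 0.10), and the list was not called (median -0.04, mean -0.03, though camera's direction was higher, adjusted p = 0.95).

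Genes of the core cardiac transcription factor list went both ways. GATA5 (-2.94 ± 0.14, adjusted p = 2.5e-09) and HAND1 (-0.84 ± 0.08) were lower. The methyltransferase gene SMYD1 (1.75 ± 0.08) and ISL1, a marker of second heart field progenitors (1.19 ± 0.08), were higher. Of the 14 genes of this list 3 rose and 5 fell (camera adjusted p = 0.17). In the sarcomere list 5 of 23 fell, including ACTC1 (-3.25 ± 0.18), MYL7 (-2.01 ± 0.10), MYH6 (-1.18 ± 0.16) and TPM1 (-0.70 ± 0.08), and 1 rose. Camera called it lower (adjusted p = 0.018), but not with an estimated correlation (adjusted p = 0.29) or after quantile normalization of the centred values (adjusted p = 0.082). The homeobox genes IRX3 (4.09 ± 0.09, adjusted p = 4e-13) and IRX5 (1.31 ± 0.08) rose in the ventricular list, of which 2 of 10 rose and 2 fell (median -0.01, mean 0.38, camera adjusted p = 0.6). In the posterior and atrial list the nuclear receptor gene NR2F1 (2.21 ± 0.09) and MEIS2 (0.92 ± 0.10) rose and MYL7 and MYH6 fell, with 3 of 13 in each direction (camera adjusted p = 0.68).

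The retinoic acid and HOX list had 4 of 14 lower, namely HOXB5 (-3.16 ± 0.09), CRABP2, a retinoic acid binding protein gene (-2.45 ± 0.20), HOXB2 (-0.95 ± 0.10) and HOXB4 (-0.62 ± 0.08), and was called by camera (adjusted p = 0.007) but not with an estimated correlation (adjusted p = 0.31). In the mesenchyme and matrix list 10 of 20 fell and 1 rose, with LUM at -2.15 ± 0.10, COL3A1 at -0.94 ± 0.15, the vimentin gene VIM at -0.90 ± 0.09 and DCN at -0.82 ± 0.09 (camera adjusted p = 2e-08, and adjusted p = 0.29 with an estimated correlation). The largest rise was that of TUBB3, the neuronal class III tubulin (4.12 ± 0.08, adjusted p = 2.8e-13). It was the single call among 13 neural genes (camera adjusted p = 0.26). Other large rises were CAMKV (3.08 ± 0.09), the carboxypeptidase gene CPE (2.82 ± 0.11), KBTBD11 (2.66 ± 0.10), HES6 (2.53 ± 0.10), the lipid transporter gene ABCA3 (2.50 ± 0.12) and SGPP2 (2.31 ± 0.15). Other large falls were RASD1 (-3.88 ± 0.11), DOK4 (-3.48 ± 0.13), the orphan receptor gene ESRRG (-3.06 ± 0.08) and EEF1A2 (-3.04 ± 0.11).

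PDPN was higher in Pop 1 by 0.94 ± 0.11 (adjusted p = 4.5e-05) and MYC by 0.83 ± 0.17 (adjusted p = 0.0043, and adjusted p = 0.068 without Pop 1 replicate 1), and NKX2-5 differed by 0.01 ± 0.10 (adjusted p = 0.99). The heat shock genes HSPA1A (1.29 ± 0.29, adjusted p = 0.0093) and HSPA1B (1.24 ± 0.31, adjusted p = 0.021), near-identical copies of each other, were higher in Pop 1 too. HSPA1A read 0.65 and 0.71 on the Pop 1 arrays and -1.07 and -0.14 on the Pop 2 arrays. Both calls were lost without Pop 2 replicate 1, where HSPA1A differed by 0.82 (adjusted p = 0.10) and HSPA1B by 0.61 (adjusted p = 0.21). They were also lost without either Pop 1 array, with robust variances (adjusted p = 0.22 and 0.3) and after quantile normalization of the centred values (adjusted p = 0.058 and 0.093). The list of 14 dissociation and heat shock genes had 3 higher and 2 lower and was not called (median -0.02, mean 0.12, camera adjusted p = 0.95). JUN was one of the lower ones (-0.90 ± 0.17, adjusted p = 0.0033), a call lost without Pop 1 replicate 1 (adjusted p = 0.063). In all 1554 genes passed, 784 higher (50.5%) and 770 lower, and 240 differed by at least 1. The count was 963 without Pop 1 replicate 1, 988 without Pop 1 replicate 2 and 2400 without Pop 2 replicate 2, and 61.4% of the calls were higher after quantile normalization of the centred values. Probes of the same gene often differed. Over the 5 comparisons, 49 of the values past the threshold under the rule for named genes belonged to genes with more than 1 probe. Another probe was called in the same direction for 19 of them and in the opposite direction for none. With the mean of a gene's probes 33 of the 49 were smaller by more than 1.5 times and 10 lost their call. In Pops 6 and 7 against Pops 2 and 3, for example, SPRY1 was then 0.62, DUSP6 0.53, ACTC1 1.04, HEY1 0.87, SLITRK4 -1.19 and LUM -1.61, and in Pop 1 against Pop 2 ESRRG was -1.3, ACTC1 -1.63, SGPP2 1.17, MEIS2 0.25 and DCN -0.28, all still called.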

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

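The tests of scaling on the gene lists and on the replicate spread, of the share of reporter-expressing cells, of the supplements and of 18S ribosomal RNA were chosen after the results they bear on had been seen, whereas the result of the splits of the arrays was predicted before. With 2 arrays per population, no population was large enough for a search for single outlying arrays.

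The difference between PDPN-positive and PDPN-negative populations was not the same in Pops 6 and 7 as in Pops 2 and 3 for 46 genes, by the interaction term in limma, with 18 to 186 genes when an array was left out. Reporter and supplement both change between these pairs, so the interaction belongs to their combination. Among the genes named, the interaction was 2.58 for MYH6, 2.43 for MYL3, 2.36 for ACTA2, 2.08 for MYL7, 2.01 for CSHL1, 1.88 for MYOM1, 1.60 for TNNC1, 1.56 for CKM, 1.39 for LUM, 0.82 for DCN, 0.81 for IRX3, 0.77 for PLN, 0.74 for NLRP7 and 0.70 for SMYD1. It was -0.66 for TGFBI, -0.73 for SOX18, -0.80 for ARHGDIB, -0.82 for ANXA1, -0.91 for CCND2, -0.97 for FOXD1, -0.98 for HAPLN1, -1.02 for MARCKS, -1.04 for COL5A2 and -1.23 for COL3A1. The call of PLN was lost without either array of Pop 1, Pop 6 or Pop 7, or without Pop 3 replicate 2. That of SMYD1 was lost without Pop 3 replicate 1 or either array of Pop 6 or Pop 7. SOX18 lost its call without Pop 3 replicate 2, either Pop 6 array or Pop 7 replicate 2, and IRX3 without Pop 6 replicate 1 or Pop 7 replicate 2. Of 31 lists 7 were called by camera in the interaction, with mean values of 0.79 for sarcomere genes, 0.40 for posterior heart field and atrial, 0.34 for smooth muscle, 0.22 for ventricular, 0.17 for endoderm and epithelium, 0.13 for excitation and calcium handling, and -0.12 for oxidative phosphorylation. With an estimated correlation the sarcomere list was still called (adjusted p = 0.001) and the others were not (adjusted p of 0.074 to 0.8). The 2 genes called in the posterior heart field and atrial list were MYH6 and MYL7, which are also sarcomere genes, and its median was 0.08.

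The first pattern weighed is the higher expression of muscle genes in Pop 6 than in Pop 7. Array-wide scaling is argued against, since the mean difference of the sarcomere list was 0.77 before and 0.66 after quantile normalization and kept its camera call. A scaling fault that depends on the signal level cannot be tested, because centring removed the levels. A lower share of NKX2-5-expressing cells in Pop 7 is argued against as the whole cause of the larger differences only. If Pop 7 were Pop 6 cells mixed with cells at the NKX2-5 level of Pops 1, 2 and 3, the median difference of the 11 called sarcomere genes (1.44) would need an NKX2-5 difference of 0.76, or 0.90 with values in natural log, whereas it was 0.20 (95% interval -0.01 to 0.40). The 11 genes were chosen by their call in this same comparison, and the smallest of their differences was 0.44. Over all 23 genes of the list the median was 0.37. Smaller differences need a smaller NKX2-5 difference, so a lower share is not argued against for them. What also stays open is that PDPN may mark more contractile cells among those with an active NKX2-5 locus, a hypothesis that these bulk values do not test.

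The second pattern is the higher expression of FGF and ERK targets in Pops 6 and 7. Array-wide scaling is argued against, with a mean list difference of 0.52 before and 0.50 after quantile normalization. A fault that depends on the signal level cannot be tested here either. The 8 arrays of these comparisons can be split into 4 and 4 in 35 ways. In a fit of 2 groups 1 of the 35, the real split, gave 2953 genes, against at most 1 gene in the others. Every other split mixes arrays with and without the reporter, so a large real difference widens its spread and leaves few calls. The arrays are also replicates of 4 populations. The splits therefore cannot exclude chance for the count, and they do not bear on the list. The supplements may account for the list. Its mean in Pop 1, also grown with SU5402 and without bFGF, lay as low as in Pop 2 (mean difference -0.03, 95% interval -0.09 to 0.03). The sorted reporter makes the same prediction, because Pop 1 lacks it as well, and the supplements and the reporter cannot be told apart for these genes. Single members did differ between Pops 1 and 2, with SPRY1 (0.81) and PHLDA1 (0.59) higher in Pop 1, CCND1 (-1.62) lower and 15 of 18 not called.

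The third pattern is the distance between the replicates of Pop 2, whose difference had an SD over genes of 0.19. Quantile normalization did not bring the Pop 2 replicates closer, since the SD was 0.19 after it too. The largest SD of the other populations was 0.16 before and 0.18 after. These SDs have no measure of error and the signal levels are lost, so a part played by scaling cannot be set aside. A different share of ribosomal RNA in a single preparation cannot be told apart from other causes: the single 18S probe differed by 2.39 between the Pop 2 arrays and by 2.42 between the Pop 1 arrays, where the SD was 0.13, yet the replicate deviations of these 2 populations correlated more than those of the other 9 pairs of populations (r = 0.26). A difference in handling or stress between replicate cultures may still be a cause and was not tested, for HSPA8 read -0.97 in replicate 1 and 0.10 in replicate 2 of Pop 2, and -0.90 and 0.23 in Pop 3.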

How the results depend on the processing

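The 4 alternatives of array medians set to 0, quantile normalization of the centred values, robust variances and the more variable genes alone were chosen after seeing the data, and the others were planned. Of 138 gene values past the threshold under the rule for named genes, 114 kept their call and direction under every alternative run. Under every alternative that kept all arrays 120 did, and none of the 138 reversed. Values named outside the rule, and the further interactions listed among the flagged results, are not part of the 138. Of 25 described list shifts called by camera, 17 kept their call under the settings other than the 2 other list tests, 20 lost it with an estimated correlation and 5 with fry. The mesenchyme list in Pop 2 minus Pop 3 had means of -0.202 to -0.029 with an array left out, and without Pop 2 replicate 2 camera placed it higher despite the mean of -0.029 (adjusted p = 0.89), for which the cause was not tested. A minimum difference of 1, which removes smaller calls by construction, left 2 calls for Pop 2 minus Pop 3, 23 for Pop 6 minus Pop 7, 18 for the interaction, 228 for Pops 6 and 7 against Pops 2 and 3, 240 for Pop 1 minus Pop 2 and 574 for any difference. The mean of a gene's probes gave 1 call and the populations of the comparison alone gave 2 for Pop 2 minus Pop 3. For Pop 6 minus Pop 7 the latter gave 203 and array weights 181, and these weights cannot part the 2 arrays of a population. Quantile normalization of the centred values gave 26 for the interaction. Pop 6 minus Pop 2 gave 1648 and Pop 7 minus Pop 3 gave 1897, with 2 arrays in place of 4 on each side. Except for the minimum difference, the cause of these moves was not tested.

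Leaving out each array in turn, with the lone array of a population assumed to vary like the rest, gave 3 to 51 calls for Pop 2 minus Pop 3, 53 to 148 for Pop 6 minus Pop 7, 18 to 186 for the interaction, 2288 to 3469 for Pops 6 and 7 against Pops 2 and 3, 963 to 2400 for Pop 1 minus Pop 2 and 2334 to 4356 for any difference. Most of the upper ends came without Pop 2 replicate 2. With the replicate number as a block the 6 counts were 4, 109, 49, 3199, 1657 and 3378, in the same order, all within 1.5 times the main ones. This block groups the arrays of all populations by number, so it is no test of a culture shared by Pops 2 and 3 alone. With such sharing, the arrays on a side of Pops 6 and 7 against Pops 2 and 3 would not all be independent, as the main model takes them to be. Also planned but not run were quantile normalization without background correction, neqc with the 75th percentile, a stricter detection filter, an intensity trend in the variances and a slide block, since they need signals, detection values or slide positions that could not be tied to the samples. The authors' values and the absence of a detection filter, planned as alternatives, are the main setting.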

Other observations

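The genes named in this part and the test of MYC targets were chosen after their values were seen, whereas the lists were fixed before. Of 13 cholesterol synthesis genes 3 fell in Pop 1 against Pop 2, namely MVD (-0.52), LSS (-0.33) and INSIG1 (-0.71), with a mean of the list of -0.34, a camera adjusted p = 0.00034 and an adjusted p = 0.67 with an estimated correlation. Without Pop 2 replicate 1 the mean was -0.10 with 1 gene called and the list was not (camera adjusted p = 0.58), and without Pop 2 replicate 2 the mean was -0.58 with 8 genes called (camera adjusted p = 2.3e-09). Without Pop 1 replicate 1 it was -0.41 with 0 genes past the threshold in limma (camera adjusted p = 3.8e-05), and without Pop 1 replicate 2 it was -0.27 with 1 gene (camera adjusted p = 0.015). In Pops 6 and 7 against Pops 2 and 3, MVD (-0.41), LSS (-0.45), SQLE (-0.39) and DHCR7 (-0.33) fell and SC5D rose (0.58), and the list was not called (adjusted p = 0.11). On the arrays the mean of the list was -0.06 and -0.20 in Pop 1, 0.45 in Pop 2 replicate 1, -0.03 in Pop 2 replicate 2, 0.24 in Pop 3 replicate 1 and 0.07 in Pop 3 replicate 2. Of 12 targets of WNT and beta-catenin signalling, AXIN2 (-0.39), LEF1 (-0.40) and DKK1 (-0.50) fell in Pops 6 and 7 against Pops 2 and 3 and none rose (camera adjusted p = 0.024, and adjusted p = 0.24 with an estimated correlation).

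Of 12 smooth muscle genes 3 rose and 3 fell in Pop 1 against Pop 2, among them ACTA2 (1.87), CNN1 (-1.07) and MYLK (-0.63), and the list was not called (camera adjusted p = 0.95). MSX1, a homeobox gene and BMP target, was higher in Pops 6 and 7 than in Pops 2 and 3 (1.51), lower in Pop 6 than in Pop 7 (-0.83) and lower in Pop 1 than in Pop 2 (-0.97). Of 15 epicardial genes 3 were lower in Pops 6 and 7 than in Pops 2 and 3, namely BNC2 (-0.84), BNC1 (-0.28) and TCF21 (-0.21), and KRT19 was higher (0.85), and the list was not called (camera adjusted p = 0.22). Of 17210 probes without a single gene name 615 differed among the 5 populations when tested as probes, as did 3863 probes with a name.

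MYC read higher in Pop 1 than in Pop 2, and a hypothesis was that MYC targets of ribosome biogenesis rise with it. Their mean difference was 0.016 (95% interval -0.12 to 0.15), with 0 of 22 genes called by limma and a camera adjusted p = 0.95, which argues against a shift of these targets beyond that interval.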
